A study of Mus musculus with 4 samples.

How the data were processed

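RNA was measured in 4 libraries from cultured mouse mammary tumour cells. The cells came from a tumour of the Chaos3 mouse, a strain that develops mammary tumours and carries a mutant allele of Mcm4, a subunit of the replicative DNA helicase. Per the labels, 2 libraries came from the parental tumour line with low Arid1a and 2 from a pair of clones given Arid1a back with a lentiviral vector. Total RNA was treated with DNase, and 500 ng per library entered a strand-specific Illumina library preparation, per the labels' protocols.

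Per the submitters' processing notes, the tools used upstream were cutadapt 1.5, TopHat2 2.0.13 and Cuffdiff 2.2.1, with the mouse genome build mm10. The gene annotation, the strand setting of the counting and the sequence of the vector insert are not given in the sources used here. The deposited table holds 1 row per gene, condition and library, and names 23361 genes by symbol. Per the file headers, it gives an estimated count of fragments per gene and library, on which the tests below were run. Of these values, 99.18% were whole numbers within a tolerance of 1e-06, and all were rounded to whole numbers before testing. The table also gives a scaled signal, in which, per the file headers, the authors' fragments are multiplied by a factor for each library. Those factors, recovered from the values, ran from 0.7291 to 1.4646. The third unit is the authors' FPKM, per kilobase of transcript and relative to sequencing depth after that scaling, per the file headers. A further 11 genes carried a failed status in at least 1 library, and 6666 genes had no fragments in any library. No column of per-sample values was left unused for want of a sample (0 such columns).

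The table names the groups as control and Arid1a and numbers the libraries within each group. The numbers 1 and 2 used here only name the libraries: which of the High libraries is which clone is not given in the table. Only the fits with the replicate number as a block, and the check of that pairing, depend on the numbering. The block is therefore an arbitrary pairing. The labels do not say that the parental duplicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels, the High group holds 1 library of each of 2 clones. Differences between clones and the effect of Arid1a add-back therefore cannot be separated within it.

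Totals per library were 13889858 and 28110812 fragments (Low) and 16523077 and 24307251 (High). A count of 3 fragments, used as the floor for a gene listed at 0, corresponds to 0.107 to 0.216 CPM (fragments scaled to a common library size), depending on the library. For a group at 0, the floor is 3 fragments over the group. Floors and the 95% intervals of fragment ratios cover counting error only. Bootstrap intervals of medians resample genes as if independent and do not measure the spread between libraries. Before groups were averaged, the duplicates were compared: chi-square per degree of freedom over genes was 34.3 for the Low pair, far above sampling noise, so these were not merged as repeats of a single library. This does not show that they are independent cultures. The High libraries are labelled as separate clones and were kept apart for that reason. The biological coefficient of variation was 17.3% within the Low pair and 42.8% within the High pair.

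The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with TMM normalisation, robust empirical Bayes and edgeR's filter on low counts (smallest count 10), and Benjamini-Hochberg adjustment at 0.05. After the filter, 12987 genes were tested, holding at least 99.91% of the fragments of each library. The fit had 2 residual degrees of freedom and a biological coefficient of variation of 32.2%. CPM values are TMM-normalised unless stated otherwise. A second fit with 3 groups (Low, and each High library alone) had 1 residual degree of freedom and a coefficient of 17.2%. It assumes that a lone High library varies like the Low duplicates. Shared control libraries were allowed for by 20 simulated sets with unchanged groups. These were drawn at the spread of that fit, which rests on the Low pair, so they do not cover the wider spread between clones. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none is given.

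A total of 34 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 28 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance in a single direction, were alternatives. With an estimated correlation, camera takes its degrees of freedom from the fit. These are 2 between the groups and 1 between the High libraries, so a list can seldom pass. A call lost there decides neither for nor against the list. With the preset, camera's p-values rest on the number of genes and do not measure the spread between libraries. Estimated correlations lay above the preset for the mitosis (0.29), luminal (0.25), mesenchymal (0.09), collagen (0.20), fibroblast (0.53) and interferon (0.96) lists. For these lists the preset p-values may be far too small. The sterol (-0.03) and milk (-0.17) lists lay below the preset. The rule named Arid1a and Mcm4, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean FPKM of at least 1 in the higher group and both High libraries on the same side of both Low libraries, and up to 4 members past the threshold, by smallest adjusted p, from each list with at least 5 tested members, with BAF subunits allowed whatever their p. Unnamed gene models were left out by that rule, and 1 gene that the rule selects is not reported here. Genes named outside it (among them Col1a1, Col3a1, Col1a2, Dcn, Cdh1, Csf1r, Lpl, Flt1, Igfbp5 and Irf7) were chosen after their values were seen. Gene positions, transcript lengths and GC content were taken from the GENCODE annotation of the mm10 assembly, matched by symbol, and 99.3% of tested genes had a value.

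The alternatives were other normalisations (relative log expression, library size alone, the authors' factors), other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), no robust step, a test against a fold of 1.5, the replicate number as a block, and each library left out in turn.

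The procedure was tested on counts simulated for 12987 genes at the means and library sizes of these data. Every library was drawn at the spread of the fit under test, so the unlike spread of the Low and High pairs was not covered. For High against Low, edgeR recovered 6.0% of genes changed 2-fold, 65.7% of those changed 4-fold and 87.9% of those changed 16-fold, with 13.1% false calls. In the same simulation, limma-voom made 10.1% false calls and DESeq2 24.7%. For High library against High library, the 3-group fit recovered 20.9%, 86.6% and 98.5% at those folds, with 4.2% false calls. That simulation used the spread of the 3-group fit (17.2%), not the 42.8% within the High pair. The 4.2% is therefore no error rate for the calls between the High libraries. For the gene lists, the shifted list was called, and 1 other list of the 28 tested was called as well. This was a single simulation with genes drawn independently, so it does not check the preset correlation. The shifted list, of collagens and matrix genes, shares members with the fibroblast list, so the other call gives no error rate.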

Results

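The transcriptome of cultured mammary tumour cells was compared between 2 libraries labelled as the parental Chaos3 tumour line, low in Arid1a, and 2 libraries labelled as a pair of clones in which Arid1a had been added back, high in Arid1a (1 per clone). Arid1a encodes a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. The libraries held 13889858 and 28110812 fragments in the Low group and 16523077 and 24307251 in the High group. Across genes, the Low duplicates correlated at r = 0.9952 on log2(CPM + 1) and the High libraries at r = 0.9776, close to the 0.973 to 0.9765 found between groups. Genes are not independent replicates, so these correlations describe the libraries only.

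Arid1a itself, chosen as a check of the labels, was lower rather than higher in the libraries labelled High, without passing the test. It can check them only if the vector's transcript was counted as mouse Arid1a, which is not known. Arid1a (ENSMUSG00000007880.16, protein-coding, minus strand of chromosome 4, 133679008 to 133756769, mm10) was at 88.2 ± 8.46 CPM (SD, n = 2) in the libraries labelled Low and at 54.1 ± 5.99 CPM (SD, n = 2) in those labelled High. The fragments behind these values were 1119 and 2574 in the Low libraries and 853 and 1432 in the High libraries. The log2 fold change was -0.71 ± 0.23 (SE), 1.63-fold lower in the libraries labelled High, and did not pass edgeR's test (adjusted p = 0.165, unadjusted p = 0.0152). Both High libraries, at 49.8 and 58.3 CPM, lay below both Low libraries, at 82.2 and 94.2 CPM. Without High library 2 the log2 fold change was -0.82 and passed the threshold (adjusted p = 0.0362, range over all alternatives 0.0362 to 0.840). Because the counted gene was not higher under the High label, every direction below is given for the libraries labelled High. None of these directions can be read as following a measured rise in Arid1a.

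Mcm4 (ENSMUSG00000022673.5, chromosome 16, 15623897 to 15637400, mm10), the helicase subunit mutated in the Chaos3 mouse, was at 238 ± 16.9 CPM in the libraries labelled Low and 150 ± 10.7 CPM in those labelled High (SD, n = 2 each). Its log2 fold change of -0.66 ± 0.22 (SE) did not pass (adjusted p = 0.171), although it did with DESeq2 (adjusted p = 0.0392, range over all alternatives 0.0392 to 0.860). Of the 25 tested BAF subunits, 0 passed edgeR's test over all genes and 0 did when adjusted over the list alone, against 4 at an unadjusted p under 0.05 and 0 with either DESeq2 or limma-voom. The log2 fold changes were -0.37 for Arid1b, the paralog of Arid1a, -0.70 for Arid2 and -0.35 for the ATPase Smarca4, with adjusted p of 0.412, 0.185 and 0.443. Across the 25 subunits, 14 had a log2 fold change below 0 and 11 above. The subunit Smarca2 set the High libraries apart, at 77.7 CPM in library 1 and 15.8 CPM in library 2. It was at 37.8 and 37.2 CPM in the Low libraries.

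**Figure D1:**
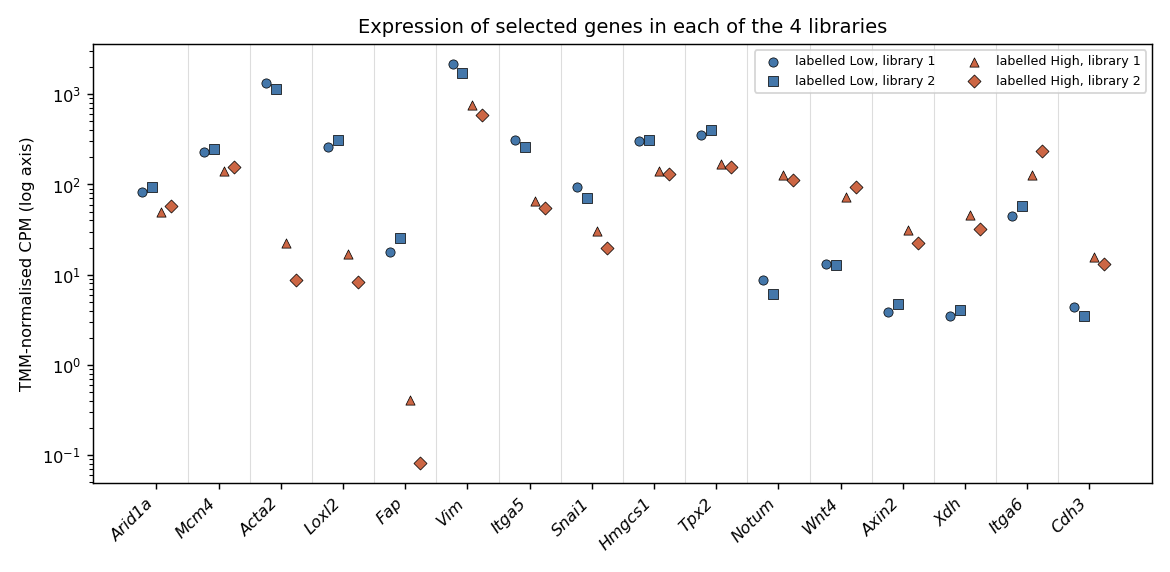
TMM-normalised CPM (log axis) of 16 genes in each of the 4 libraries, with blue points for the libraries labelled Low and orange points for those labelled High. Arid1a and Mcm4 lie lower in both High libraries without passing the test, and for the other genes shown, such as Acta2, Fap and Notum, the High libraries lie apart from the Low libraries.

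The next question was which genes differ between the libraries labelled Low and those labelled High. Smooth-muscle actin (Acta2), the matrix cross-linking enzyme Loxl2 and the fibroblast marker Fap fell in the libraries labelled High, while the Wnt feedback inhibitor Notum, the uroplakin Upk1b and the milk-fat secretion gene Xdh rose. Acta2 (chromosome 19, 34241090 to 34255590, mm10) fell from 1236 ± 118 to 15.7 ± 9.96 CPM (SD, n = 2 each), a 79.2-fold difference (adjusted p = 0.00976). Notum (chromosome 11, 120653788 to 120661175, mm10) rose from 7.41 ± 1.78 to 120 ± 10.4 CPM, 16.3-fold (adjusted p = 0.0021). In all, 148 genes rose and 173 fell of 12987 tested by edgeR, all 321 by at least 2-fold, 95 of the rises and 128 of the falls by at least 4-fold. In every called gene both High libraries lay on the same side of both Low libraries, which held for 51% of tested genes. Chance gives 33.3% only if all 4 libraries vary alike. The coefficient of variation was 17.3% within the Low pair and 42.8% within the High pair, which can raise that share. The 51% is therefore not read as an excess over chance. With either Low library left out, edgeR called 0 genes (1004 at an unadjusted p under 0.05 without Low library 1, 840 without Low library 2), and every call named in the text was lost, whereas 2226 genes were called without High library 1 and 2446 without High library 2. On all 4 libraries, the unadjusted count was 2348, DESeq2 called 1136 genes, limma-voom 217 and limma on log2(FPKM + 1) 287. Of the 60 genes chosen by the naming rule and called by edgeR, limma-voom did not call 14: Ccl11, Slc6a12, Tlr1, Pmaip1, Ddit4l, Itga6, Cdh3, Egfr, Lama4, L1cam, Tgfb1, H2-T23, Areg and Cspg4.

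Among the 12 largest rises, 4 genes had no fragments in either Low library after rounding (for Akr1b3 the estimates before rounding were 0.00658 and 0.00609). Upk1b, a uroplakin of the urothelial surface, stood at 9.32 ± 5.07 CPM in the libraries labelled High (SD, n = 2), at least 118-fold higher (adjusted p = 0.00976). Upk3b, a related surface protein, was at least 31.8-fold higher, Ttc36 at least 30.1-fold and the aldose reductase gene Akr1b3 at least 35-fold. Akr1b3 has close copies in the genome, and its counts are uncertain for that reason. Serpinb2, an inhibitor of plasminogen activators, rose from 0.752 ± 0.287 to 42.5 ± 12.3 CPM, 58.4-fold (adjusted p = 0.0021). The other rises were the adhesion molecule Nrcam (50.3-fold), the betaine transporter Slc6a12 (44.9-fold), the surface antigen Psca (36.1-fold) and Ugt1a6b (71.1-fold), whose exons are largely shared with neighbouring Ugt1a genes, so that its counts are uncertain. With 2 or 3 fragments in the Low group, the ratio was 107 for the kinase Mapk4 (interval 29.3 to 890), 94.3 for the eosinophil chemokine Ccl11 (25.8 to 784) and 37.7 for the innate receptor Tlr1 (12.6 to 185).

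Among the 12 largest falls, Ptx3, a secreted pentraxin of innate defence, went from 54.2 ± 4.84 to 0.149 ± 0.0376 CPM (SD, n = 2 each), 359-fold lower (adjusted p = 7.57e-04). Dkk2, a secreted Wnt antagonist, had 1564 fragments in the Low group and 2 in the High group, a ratio of 796 (95% interval 220 to 6579). No fragments were found in either High library for the ion channel Trpa1 (at least 111-fold lower), the secreted matrix protein Cthrc1 (at least 83.1-fold), the receptor Il1rl2 (at least 49.9-fold), the growth factor Ptn (at least 27.2-fold) and the granzymes Gzmc, Gzmd and Gzmb (at least 46.8-, 47.5- and 25.4-fold). Granzyme genes are close copies of each other, so the split of fragments among them is uncertain. A single fragment remained in the High group for the cadherin Cdh10 (ratio 509, interval 90.9 to 20140), the potassium channel Kcnh1 (316, 56.2 to 12500) and the neuronal stathmin Stmn2 (231, 41.1 to 9167).

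**Figure D2:**
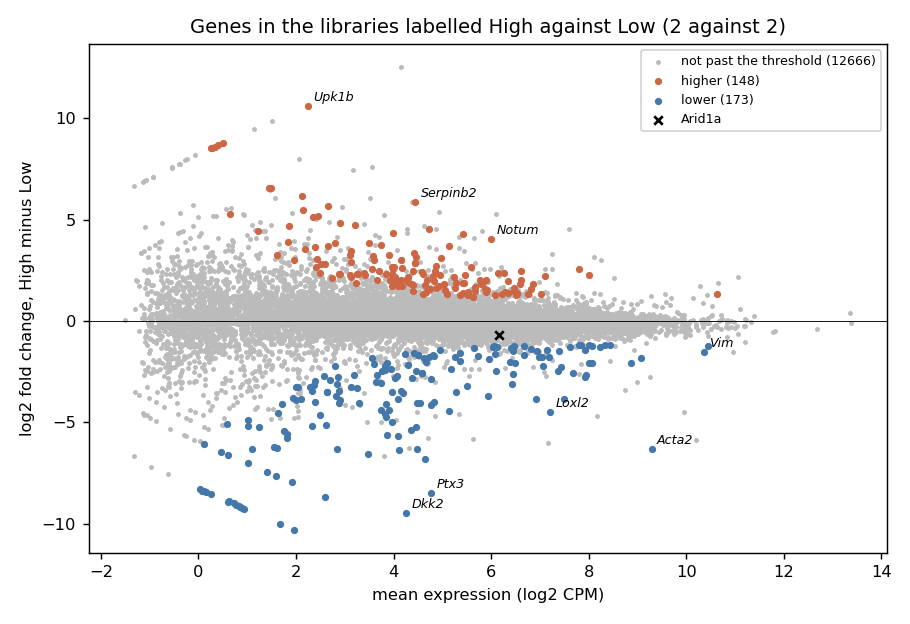
Log2 fold change (labelled High minus labelled Low) against mean expression (log2 CPM) for 12987 tested genes. Orange points mark the 148 genes that rose, blue points the 173 that fell, grey points those not past the threshold, and a cross Arid1a, whose log2 fold change of -0.71 did not pass.

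The lists of matrix and mesenchymal genes held more falls than rises. Of 28 collagen and matrix genes tested, 4 fell, 0 rose and 24 did not pass (8 fell when adjusted over the list alone). The lysyl oxidase Loxl2 fell 22.4-fold (284 ± 37.0 to 12.7 ± 6.27 CPM, SD, n = 2 each, adjusted p = 0.00574), the fibrillin gene Fbn1 14.6-fold (adjusted p = 0.0316), the laminin chain Lama4 8.58-fold (0.0481) and the anchoring-fibril collagen Col7a1 4.23-fold (0.0233). The median log2 fold change was -1.04 (-1.64 without High library 1), and camera called the list lower (adjusted p = 7.05e-06), with adjusted p = 0.671 with an estimated correlation. Col1a1 was at 2520.5 and 2133 CPM in the Low libraries against 63.5 and 16.1 CPM in the High libraries and missed the threshold (adjusted p = 0.0717). Among 22 mesenchymal genes, 4 fell, 0 rose and 18 did not pass, while adjusted over the list alone 4 fell and 1 rose. The fallers were the fibronectin receptor Itga5 (4.8-fold, adjusted p = 0.00622), the gelatinase Mmp9 (3.69-fold, 0.0104), vimentin, Vim (2.88-fold, 0.0275), and the transcription factor Snai1 (3.25-fold, 0.0340). That list had a median of -1.01 (-0.61 without High library 2) and was called lower by camera (adjusted p = 0.00117), with adjusted p = 0.671 with an estimated correlation.

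Fibroblast and pericyte markers went both ways, 6 of 9 with a log2 fold change below 0 and 3 above. Of these, 2 fell and 7 did not pass (3 fell and 1 rose when adjusted over the list alone). The serine protease Fap fell 93.6-fold (21.8 ± 5.49 to 0.245 ± 0.232 CPM, SD, n = 2 each, adjusted p = 0.00738) and the proteoglycan Cspg4 14.9-fold (adjusted p = 0.0424). The median was -2.59 and camera called the list lower (adjusted p = 0.0295), with adjusted p = 0.671 with an estimated correlation, and the call was also lost without High library 2 (median -1.64, adjusted p = 0.0621). Decorin, Dcn, went the other way at 4.19 and 5.45 CPM in the Low libraries and 195 and 19.6 CPM in the High libraries, without passing (adjusted p = 0.251). Col1a1, Col3a1, Postn and Dcn stand in both this list and the matrix list.

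In the mitosis and sterol lists few genes passed, and by smaller folds. All 25 tested mitosis genes had a log2 fold change below 0, with a median of -0.67, but only Tpx2, a spindle assembly factor, fell past the threshold over all genes (2.33-fold, adjusted p = 0.0340), against 14 adjusted over the list alone. Camera called the list lower (adjusted p = 4.16e-06), with adjusted p = 0.671 with an estimated correlation. Among 22 genes of cholesterol synthesis, 2 fell and 20 did not pass, and 7 fell when adjusted over the list alone. Hmgcs1, an enzyme early in the pathway, fell 2.27-fold (308 ± 8.65 to 136 ± 5.01 CPM, SD, n = 2 each, adjusted p = 0.0349). With the replicate number as a block, both of these calls were lost (adjusted p = 0.0523 for Tpx2 and 0.0585 for Hmgcs1, ranges over all alternatives 2.87e-06 to 0.666 and 3.6e-06 to 0.661). The sterol list had a median of -0.59 and was called lower by camera (adjusted p = 2.17e-05), with adjusted p = 0.671 with an estimated correlation, and it was the only list called by fry (adjusted p = 0.00919).

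In the luminal and milk lists 1 gene passed. Of 20 luminal genes, 0 passed over all genes with edgeR, against 8 at an unadjusted p under 0.05, 5 with DESeq2 (4 higher, 1 lower) and 0 with limma-voom. Adjusted over the list alone, 1 rose and 1 fell. E-cadherin, Cdh1, was at 130 and 146 CPM in the Low libraries and 263 and 386 CPM in the High libraries (adjusted p = 0.0576). The luminal median was 1.06 and camera called the list higher (adjusted p = 0.0384), with adjusted p = 0.671 with an estimated correlation, and the call was lost without Low library 1 (0.0557), Low library 2 (0.0822) or High library 2 (0.195), where the median was 0.42. Of 5 tested milk and secretory genes, 1 rose and 4 did not pass, with 3 rising when adjusted over the list alone. The riser, Xdh, needed for milk-fat secretion, went from 3.79 ± 0.378 to 39 ± 10 CPM (SD, n = 2 each), 10.2-fold (adjusted p = 0.00466). The milk list had a median of 1.66, and 0.89 without High library 2 (camera adjusted p = 0.00878, adjusted p = 0.671 with an estimated correlation), and the caseins Csn1s1, Csn1s2a and Csn2 were listed at 0 in every library.

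**Figure D3:**
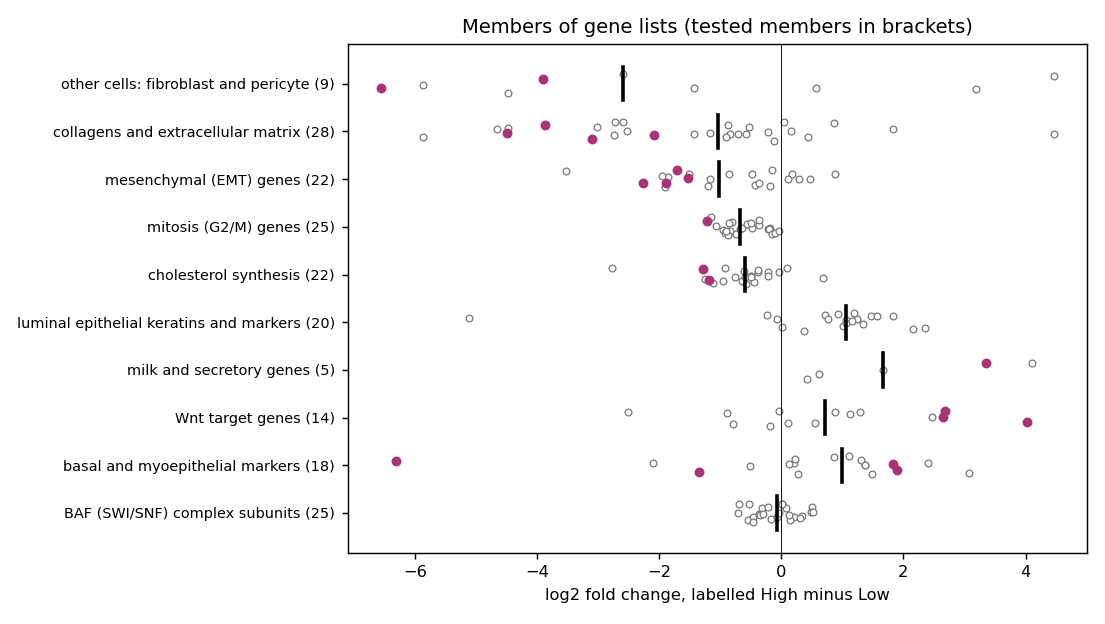
Log2 fold change (labelled High minus labelled Low) of the tested members of 10 gene lists, with filled points for members past the threshold, open points for the others and a black bar at each list's median. The fibroblast list has the lowest median of those shown, -2.59, and the milk list the highest, 1.66.

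Basal and adhesion genes split in direction. Among 18 basal and myoepithelial genes, Acta2 (79.2-fold) and the growth factor receptor Egfr (2.55-fold) fell, while the laminin receptor subunit Itga6 (3.54-fold) and P-cadherin, Cdh3 (3.71-fold), rose, and 14 did not pass (7 rose and 3 fell when adjusted over the list alone). Camera did not call this list (adjusted p = 0.199, and 0.0293 to 0.762 with a library left out), but called it higher without High library 1. Among 18 integrins and adhesion molecules, Itgb6 rose 5.47-fold, and Alcam (7.25-fold), L1cam (3.14-fold) and Itgb3 (16.4-fold) fell, 14 not passing (4 rose and 4 fell when adjusted over the list alone, camera adjusted p = 0.455). Several of these calls depended on the processing. Of 17 alternatives, 7 kept the call of Cdh3 (adjusted p from 5.49e-06 to 0.765), 8 that of Egfr (1.15e-05 to 0.764) and 9 that of Itga6 (8.79e-13 to 0.686), and limma-voom called 0 rises and 1 fall (Acta2) among the basal genes.

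Of 14 Wnt target genes, 3 rose and 11 did not pass (5 rose and 2 fell when adjusted over the list alone). Besides Notum these were the ligand Wnt4 (13 ± 0.399 to 83.2 ± 15.3 CPM, 6.39-fold, adjusted p = 0.00412) and Axin2, a negative-feedback component of the pathway (6.26-fold, 0.0118). The list missed the threshold (median 0.72, camera adjusted p = 0.0675), but was called higher without High library 1 (median 0.97, adjusted p = 0.02925), against a median of 0.45 without High library 2 (0.195). Among 20 TGF-beta responsive genes, the differentiation inhibitor Id2 rose 3.66-fold, and the matricellular factor Ctgf (3.53-fold) and the ligand Tgfb1 (2.54-fold) fell, with 17 not passing (3 rose and 3 fell when adjusted over the list alone, camera adjusted p = 0.455). The call of Tgfb1 was kept in 8 of 17 alternatives (adjusted p from 4.04e-05 to 0.620).

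Single members passed in several further lists that camera did not call. Of 24 p53 targets, the stress gene Gadd45a (3.31-fold) and the pro-apoptotic Pmaip1 (4.0-fold) rose and Ddit4l, an inhibitor of mTOR signalling, fell (4.58-fold), with 5 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.388). The chemokine Ccl2 fell 2.78-fold, the only one of 21 cytokines to pass (1 rose and 1 fell when adjusted over the list alone). The cytokine median was -0.13 but the mean 0.08, and camera's direction was down (adjusted p = 0.242). The angiogenic factor Vegfa fell 2.69-fold among 24 glycolysis and hypoxia genes (2 fell when adjusted over the list alone, camera adjusted p = 0.137, but 0.0282 without Low library 2, range 0.0282 to 0.411 with a library left out). The ferritin heavy chain Fth1 rose 2.56-fold among 19 NRF2 and glutathione genes (2 when adjusted over the list alone, camera adjusted p = 0.609), and the EGFR ligand Areg 3.52-fold among 18 growth factors (1 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.242). The non-classical class I molecule H2-T23 rose 2.65-fold among 14 antigen presentation genes (1 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.339). The call of H2-T23 was kept in 7 of 17 alternatives (adjusted p from 2.36e-06 to 0.764) and that of Areg in 11 (5.04e-09 to 0.696), with limma-voom calling neither.

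In the remaining tested lists 0 members passed over all genes with edgeR. The 28 replication genes had a median of -0.17 (camera adjusted p = 0.0849, 5 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom), which became -0.44 and a call without High library 2 (adjusted p = 0.0313) and -0.08 without High library 1 (0.681), and the 23 break repair genes -0.16 (0.242, with 3, 1 and 0). The 25 interferon-stimulated genes had a median of 0.99 (0.626, with 3, 1 and 0), but the direction depended on the library: the median was -1.15 without High library 1 (adjusted p = 1.67e-06) and 1.81 without High library 2 (2.46e-09). The 23 unfolded protein and stress response genes had a median of 0.16 (0.455, with 5, 2 and 0), the 21 PI3K-AKT regulators -0.0029, with a mean of 0.04 and camera's direction down (0.886, with 4, 2 and 0), the 20 immediate early genes 0.16 (0.242, with 3, 1 and 0) and the 20 apoptosis regulators -0.10 (0.455, with 4, 2 and 0). The 8 histone genes had a median of -0.43 (0.242, with 1, 1 and 0), and the 10 nuclear-retained and non-coding RNAs 0.47 (0.242, with 2, 0 and 0). The 28 ribosomal protein genes had a median of 0.02, a mean of -0.05 and camera's direction down (0.609, with 0, 0 and 0). Adjusted over the list alone, 1 stress response gene rose, 1 apoptosis regulator fell and 0 genes of the other lists in this paragraph passed. The BAF list had a median of -0.07 (camera adjusted p = 0.242), and -0.23 without High library 1. With a library left out, the histone median ran from -0.81 (Low library 2) to -0.03 (Low library 1). That of the nuclear-retained and non-coding RNAs ran from 0.20 (High library 1) to 0.80 (Low library 2). Without Low library 2 the stress response median was 0.0008, and without Low library 1 the immediate early median was 0.37. Without Low library 2 the sign of the median changed for break repair (0.04), PI3K-AKT (0.25), apoptosis (0.01) and ribosomal protein genes (-0.21), and without High library 2 for PI3K-AKT (0.0055) and ribosomal protein genes (-0.28).

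Most markers of blood, vessel and fat cells were too low to be tested. Of 19 leukocyte genes 3 were tested and 0 passed (1 at an unadjusted p under 0.05 and adjusted over the list alone, 1 with DESeq2, 0 with limma-voom). The highest in the libraries labelled High was the receptor Csf1r, at 8.67 CPM in both Low libraries and at 20.8 and 27.4 CPM in the High libraries (adjusted p = 0.0579), and Ptprc, the pan-leukocyte gene, had at most 0.285 CPM before TMM scaling. Of 15 lymphocyte genes 2 were tested and Gzmb fell, while the T-cell gene Cd3e was listed at 0 in every library. Of 14 endothelial genes 4 were tested and Flt1, a receptor for vascular growth factors, fell 3.18-fold, from 42.6 ± 6.18 to 13.4 ± 1.45 CPM (SD, n = 2 each, adjusted p = 0.0272), whereas Pecam1 had at most 0.605 CPM before TMM scaling. Adjusted over their lists alone, 1 lymphocyte and 1 endothelial gene fell. Of 10 adipocyte genes 3 were tested and 0 passed, over all genes or the list alone (1 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). Lpl, a lipase of fat and mammary tissue, was at 2.86 and 4.79 CPM in the Low libraries and 81.7 and 16.2 CPM in the High libraries (adjusted p = 0.191). No red-cell gene was tested (0 of 9), nor was any mitochondrially encoded gene (0 of 11). The mitochondrially encoded genes were not listed in the deposited data under the symbols used, so their level is unknown. The ribosomal RNA precursor Rn45s took 0.860% and 0.900% of fragments in the Low libraries and 1.05% and 1.38% in the High libraries.

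The High libraries are labelled as 2 separate clones, so each was also compared with the Low pair and with the other. In the 3-group fit, 1389 genes rose and 1063 fell in High library 1, and 1189 rose and 1058 fell in High library 2. Both libraries rose for 572 genes and fell for 477, and 112 genes went in opposite directions. Independent lists of these sizes would share 127 rises and 86.6 falls. Simulated unchanged groups that share control libraries shared 0. Each simulated High library alone gave a mean of at most 0.05 calls per direction, so a shared 0 was fixed in advance. The simulation used the spread of the 3-group fit (coefficient 17.2%), not the 42.8% of the High pair. Its values therefore do not cover ordinary differences between clones. All 321 genes called between the groups were called in the same direction in both High libraries. This was largely settled by their selection, since both High libraries already lay on the same side and the 3-group fit assumes a smaller spread. It is no separate evidence that the clones agree. The log2 fold changes had the same sign for 68.4% of genes (simulated 60.9%) and correlated across genes at r = 0.587 (simulated 0.324), with a covariance of 1.10 (simulated 0.0507). With only 2 control libraries these could not be split, so part of the excess over independent lists may come from the shared controls.

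Between the High libraries, 1419 genes differed, 579 higher and 840 lower in High library 2. The insulin-like growth factor binding protein Igfbp5 was at 266 CPM in High library 1 and 0.0407 CPM in High library 2, against 2.64 and 4.13 CPM in the Low libraries. Col3a1 was at 169 against 2.04 CPM, whereas Col1a2 went the other way, at 14.5 against 304 CPM. Among 25 interferon-stimulated genes, 20 rose in High library 1 (median log2 fold change 1.81), and 13 fell in High library 2 (median -1.15). Between these libraries 22 of them differed, all lower in High library 2, with a median difference of -2.70 (camera adjusted p = 6.77e-24, adjusted p = 0.795 with an estimated correlation). Irf7, a transcription factor of the interferon response, was at 31.1 CPM in High library 1 and 1.99 CPM in High library 2, against 3.01 and 2.71 CPM in the Low libraries. These tests set single libraries against each other, and neither has a replicate.

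**Figure D4:**
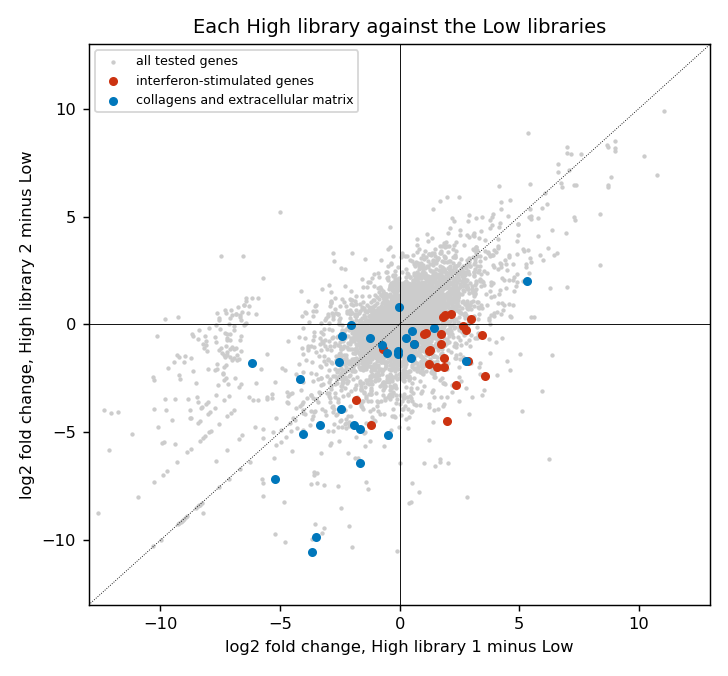
Log2 fold change against the Low libraries in High library 1 (horizontal) and High library 2 (vertical) for all tested genes in grey, interferon-stimulated genes in red and matrix genes in blue, with the dotted line marking equal values. Interferon-stimulated genes have a median of 1.81 on the horizontal axis and -1.15 on the vertical axis.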

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

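Of the tests weighed in this part, those for GC content and transcript length were fixed before their results were seen, and the others (condition names, the region of chromosome 4, the vector transcript, fibroblasts and leukocytes) were chosen after the result was seen.

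Between the High libraries, 1419 genes differed in the 3-group fit, which sets 1 library against 1 and borrows the spread of the Low pair. At the level of lists, tests of the difference between these libraries stood out for 6 lists, given as the median log2 value of High library 2 minus High library 1. They were luminal markers at 1.23, collagens and matrix at -1.32, TGF-beta responsive genes at -0.521, interferon-stimulated genes at -2.70, ribosomal proteins at 0.518 and fibroblast markers at -2.25. With an estimated correlation, camera called 0 of these 28 tests between High libraries, with 0 at an unadjusted p under 0.05. That version had 1 residual degree of freedom and could hardly call any list, so it does not decide the question.

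Arid1a, the gene added back per the labels, was lower in both libraries labelled High. A loss of most of the region of chromosome 4 within 2 Mb of Arid1a is argued against. The other 71 tested genes there had a median log2 fold change of -0.0754 (95% bootstrap interval over genes -0.199 to 0.0985). That median lay above -0.35, the bound set for a shared loss from the fall of Arid1a itself. A loss of Arid1a alone, or with few neighbours, would hardly move it and stays open. Swapped condition names stay open: the coefficient of variation within the High pair was 2.47 times that of the Low pair, which is how a pair of clones and a pair of duplicates might differ, but it cannot exclude a swap. A vector transcript that was not counted as mouse Arid1a also stays open, since the counted gene was 1.63-fold higher in Low and the insert is not described in the sources used here. A lower level of endogenous Arid1a in the selected clones was not tested.

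Mesenchymal, collagen and fibroblast-marker lists were called lower in the libraries labelled High by camera, though not with an estimated correlation (adjusted p = 0.671 for each), and 4 of 22, 4 of 28 and 2 of 9 members passed over all genes. The fibroblast call was also lost without High library 2 (adjusted p = 0.0621). A trend with GC content or transcript length is argued against, since the median of the first 2 of these lists (50 genes) was -1.08 after both trends were removed (interval -1.82 to -0.608), against -1.04 before. Fewer fibroblast-like cells stay open in both High libraries. In the 3-group fit, 3 of the 9 tested fibroblast markers rose in High library 1 (Dcn, Pdgfra and Mfap5) and 1 of 9 in High library 2 (Dcn), too few, and each from a single library, to exclude a smaller share of such cells, so this cannot be told apart from a change within the tumour cells. With the condition names as given, the add-back itself, exposure to the lentiviral vector and the selection of single clones remain explanations that this design does not separate. No library is labelled as given an empty vector.

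Interferon-stimulated genes were higher in High library 1 than in High library 2 (adjusted p = 0.795 with an estimated correlation). Leukocytes in High library 1 are argued against, by a bound chosen after the result. Only 2 of the 19 leukocyte genes (Cd68 and Ctss) reached 1 CPM there without doing so in the Low libraries, while Ptprc, Tyrobp and Laptm5 were listed at 0. Csf1r and Cd14, above 1 CPM in the Low libraries, could not count. Before TMM scaling, Csf1r was at 21.5 CPM in High library 1 and 27.7 in High library 2, against 8.5 and 8.43 in the Low libraries. Cd14 was at 15.6 and 24.1 CPM, against 17.2 and 11.8. A trend with GC content or transcript length is also argued against, with a median of -2.64 after correction (interval -3.54 to -2.09) over 25 genes. A difference between the clones, or between the cultures on the day of harvest, remains a hypothesis that could account for it and was not tested.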

How the results depend on the processing

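The crossed pairing was chosen after seeing the data, and all other alternatives before. The count of 321 genes became 814 with no filter, 1136 with DESeq2, 191 against a fold of 1.5 and 0 with limma on log2(FPKM + 1) without a filter (2468 at an unadjusted p under 0.05), and 0 to 2446 with a library left out. Without a Low library the spread rests on the High pair alone, without a High library on the Low pair. It was 217 to 370 under the other settings without a block. Rises were 46.1% of the calls, but 33.2% with limma-voom (72 higher, 145 lower), 35.6% against a fold of 1.5 (68, 123) and 38.1% and 38.3% with the filtered limma fits on FPKM, against 52.1% with library size alone (182, 167), 53.7% with no filter (437, 377), 53.8% with DESeq2 (611, 525) and 52.7% and 56.0% without High library 1 and 2. The cause was not tested for these settings. The replicate number as a block gave 469 genes (304 shared); deviations of same-numbered libraries correlated at -0.139 across genes, so the numbers do not pair the libraries, and crossed pairing gave 94 (88 shared). Of 60 called genes chosen by the naming rule, the block ended the calls of 3 (Tpx2, Cdh3 and Hmgcs1), limma-voom 14, the fit without the robust step 12, limma on log2(FPKM + 1) 13, on log2(FPKM + 0.1) 14 (with 59 of the 64 named genes tested there), the test against a fold of 1.5 26, the authors' factors 2, library size alone 2, relative log expression factors 1, and the other edgeR filters, DESeq2 and leaving out either High library 0. Limma on log2(FPKM + 1) without a filter and leaving out either Low library ended all 60. The calls of Ccl11, Itga6, Cdh3, Egfr, Lama4, Tgfb1 and H2-T23 ended in each of limma-voom, both filtered FPKM fits, the fit without the robust step and the test against a fold of 1.5.

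Arid1a was lower in the libraries labelled High under all 17 alternatives (log2 -0.82 to -0.60 with a library left out), passing only without High library 2, where it was -0.82. The 7 called lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry (7 unadjusted), and 6 to 10 with a library left out. Genes with a 2-fold difference between the High libraries, without a test, numbered 2445 against 1419 called. Genes shared by both High libraries numbered 1022 to 1298 under their 3 alternatives. The 3-group fits could not be repeated without a Low library, which leaves no residual degrees of freedom. No named gene or called list changed direction under the alternatives run for it. With these libraries 2-fold changes were mostly missed: 6.0% were recovered in simulation.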

Other observations

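The tests in this part were all chosen after the data were examined. Gene families, grouped by the stem of the gene symbol, were compared with all tested genes in 754 one-sided Fisher's exact tests over 377 families, and 4 passed after adjustment. Granzymes, the proteases of cytotoxic granules, fell in 4 of 5 tested members (Gzmb, Gzmc, Gzmd and Gzme, adjusted p = 1.13e-04, lower in both High libraries), but these genes are close copies with an uncertain split of fragments, so the test overcounts them if they are not separate events, while the T-cell genes Cd3e and Cd8a were listed at 0 in every library. Glucuronosyltransferases rose in 3 of 5 (Ugt1a6a, Ugt1a6b and Ugt1a9, adjusted p = 0.00538), but these genes share exons, so they are not separate events. The Armcx genes of the X chromosome fell in 3 of 6 (Armcx2, Armcx4 and Armcx6, adjusted p = 0.0113), and Wnt ligands rose in 3 of 10 (Wnt4, Wnt6 and Wnt7a, adjusted p = 0.0309). Hox genes (3 of 14 fell, adjusted p = 0.0954) and matrix metalloproteinases (3 of 13 fell, 0.0908) did not pass.

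Median expression also differed by chromosome. Only tested genes above a minimum mean expression were used here, and each median is given relative to that of all genes used. In High library 2 the 283 genes used on chromosome 12 had a median log2 fold change of 0.48. It lay between 0.32 and 0.61 in each of 5 nearly equal groups of genes along the chromosome, against -0.03 for the chromosome in High library 1. Chromosome 14 stood at 0.31 in High library 1 and -0.14 in High library 2, chromosome 15 at -0.34 and -0.22, chromosome 2 at -0.22 and -0.34, and chromosome 5 at 0.12 and 0.34. The others lay between -0.25 and 0.28. A comparison with random gene sets passed for 37 of the 40 medians, so it does not set any chromosome apart, and the values are given without an explanation.

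Chosen after their values were seen, several growth factor genes also set the High libraries apart. Igf1 was at 92.5 CPM in High library 1 and 2.36 CPM in High library 2, against 1.54 and 2.09 CPM in the Low libraries, and Igf2 at 33.6 and 0.244 CPM, against 2.94 and 5.71 CPM. The cartilage collagen Col2a1 was at 537 and 17.8 CPM, against 32.5 and 23.4 CPM, and Postn at 124 and 4.44 CPM, against 355 and 416 CPM.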
